A study of Caenorhabditis elegans with 2 samples.

How the data were processed

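The data were peak lists from ChIP-seq of eGFP-tagged NHR-237 in mixed-stage C. elegans embryos, with 2 biological replicates in a single group and a library size range of 150 to 350 bp per the labels. For each replicate the authors deposited a list of peaks and background regions made as input for the IDR procedure. For both replicates together they deposited a pooled list and an optimal IDR list, each on builds ce10 and ce11. Per the deposited text listings, the replicate and pooled lists were called against a control alignment. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each peak was deposited by the authors as their caller wrote it, and it was not scaled between lists. The −log10 of the q-value per peak was deposited in the replicate and IDR lists; 595 of the 1626 IDR peaks tied at its highest value, 2.38, so peaks were ranked by signal value. The control alignment and read-level files were not analysed here.

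The lists were read as deposited, and positions are on ce11, given 1-based. No peak end lay beyond a chromosome of the WBcel235 reference, whose sequence was used with Ensembl release 115 gene models. The ce10 lists served only for counts and overlap, with no conversion of coordinates; random placements for ce10 used the chromosome lengths of ce11. The deposited summit was the midpoint of the peak for 1531 of 1626 IDR peaks, or 94.2%, which limits how closely windows centred on it follow the point of highest signal. The 15 IDR peaks on the mitochondrial genome were left out of the promoter, chromosome share, gene list and motif comparisons.

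Groups, tests, gene lists, motifs, alternatives and the rule for named genes were fixed before the data were examined. Overlap required 1 bp and was tested against 1000 random placements within chromosomes. Signal values were compared across peaks with summits within 100 bp, with 100000 permutations. A promoter ran from 500 bp upstream to 200 bp downstream of the 5′ end of a protein-coding transcript. Its share was tested against 10000 random placements and, by Fisher's exact test, against summits of pooled-list peaks that no IDR peak overlapped, adjusted over 4 annotation classes. A summit could be counted for several genes: 333 of 1013 promoter summits, or 32.9%, lay in the window of more than 1 gene. Gene lists were tested with Fisher's exact test, two-sided, against all nuclear genes of the same class, with Benjamini-Hochberg adjustment over 24 lists and a threshold of 0.05. Genes are not independent where they share a peak. Motifs on either strand were compared within each peak between the central 100 bp and 2 flanks of 50 bp by the exact McNemar test. Intervals are 95% Clopper-Pearson intervals for shares and exact conditional intervals for odds ratios, and cover counting error only. All p-values treat peaks or genes as units and say nothing of variation between embryo preparations.

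Named genes were those with promoters at the 15 IDR peaks of highest signal, nhr-237 and unc-119, and up to 4 members of highest signal in each list that passed its test and in the nuclear receptor, intestine, hypodermis, muscle, pharynx and neuron lists. Named 6-mers were the 5 of largest ratio among those past the threshold and present at 5% or more of the centres. Symbols that matched no annotated gene were left out of the lists. The other chemosensory receptor gene that the rule names is not reported here.

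Alternatives were other overlap rules and matching distances, ce10, the 813 IDR peaks of higher signal, other promoter windows, the peak midpoint, other backgrounds, the nearest gene within 2000 bp, other motif flanks, and the top peaks of each replicate alone, as many as the IDR list holds. Autosomal peaks only were added after the data were seen. The scripts were tested on simulated data. For the promoter comparison, 60.1% of 1611 simulated summits were planted in promoters and 60.1% were recovered. For the gene list comparison over 19973 genes, 10 planted lists were called and 0 of 10 unchanged lists. With no motif planted at 1611 random positions of the nuclear chromosomes, 0 fixed motifs were called. Those positions were not matched for the GC difference between real centres and flanks, so this result says nothing of calls that follow from composition. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.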

Results

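Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the genomic sites occupied by NHR-237, a member of the nuclear hormone receptor family, in mixed-stage embryos of the nematode Caenorhabditis elegans. The strain, OP228, carries an integrated transgene that expresses NHR-237 fused to enhanced green fluorescent protein (eGFP) in an unc-119 mutant background. The samples formed a single group of 2 biological replicates, prepared from whole embryos of both sexes. Read counts were not analysed here, so the depth of each library is unknown, and the number of peaks is the only size given for each sample. On genome build ce11, the list of replicate 1 held 10872 peaks and that of replicate 2 held 30000 peaks. A list called on both replicates together, named the pooled list here, held 30000 peaks. The list that passed the irreproducible discovery rate (IDR) procedure, which rests on how alike peaks rank between lists, held 1626 peaks with a median width of 396 bp. Not every peak in it was overlapped by a peak of each replicate. On build ce10 the same IDR list held 1675 peaks. The replicate and pooled lists hold peaks and background regions made as input for the IDR procedure. On ce11 the lowest −log10 q was 0.018 in replicate 1 and 0.022 in replicate 2. The replicate 2 and pooled lists held 30000 on ce10 too, which may be a limit on list length. The lengths of these input lists therefore do not count binding sites. The signal value of a peak is the value the authors' peak caller gave it, and it was used to rank peaks within a list and, for matched peaks of the replicates, in a correlation. No group without the tagged protein was analysed here, so every comparison sets peaks against other positions of the genome or against other peaks.

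The first comparison asked how far the peaks of the replicates coincided. Of the replicate 1 peaks, 7021 of 10872, or 64.6% (95% Clopper-Pearson interval 63.7 to 65.5), overlapped a replicate 2 peak by at least 1 bp. Random placements of the same peaks within chromosomes gave a mean of 21.1% and at most 22.3% (one-sided permutation p = 0.001, the smallest that 1000 placements can give). In the other direction, 7706 of the 30000 replicate 2 peaks, or 25.7% (25.2 to 26.2), overlapped a replicate 1 peak. No random placements were run for that direction. Among the 1626 peaks of highest signal in each list, 71.6% of the replicate 1 peaks overlapped a replicate 2 peak, against a mean of 1.65% in random placements. Across 4764 peaks whose summits lay within 100 bp of each other, signal values had a Spearman's rho of 0.705 and, on the log2 scale, a Pearson's r of 0.800 (permutation p = 1e-05 for both, the smallest that 100000 resamples can give). These coefficients are across peaks, which are not independent replicates. Of the IDR peaks, 1602 of 1626, or 98.5% (97.8 to 99.1), were overlapped by a peak of each replicate. The IDR procedure selects on agreement between lists, so this share is high partly by construction. The 1626 IDR peaks were exactly the 1626 highest peaks of the pooled list by signal value.

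IDR peaks lay mainly just upstream of protein-coding genes. Of 1611 summits on the nuclear chromosomes, 1013, or 62.9% (60.5 to 65.2), fell between 500 bp upstream and 200 bp downstream of the 5′ end of a protein-coding transcript. Random placement within chromosomes gave a mean of 16.2% and at most 19.5% (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). Summits of the 28038 nuclear pooled-list peaks that no IDR peak overlapped were in promoters in 20.7% of cases, an odds ratio of 6.48 (Fisher's exact test, adjusted exact p = 5.16e-273). The pooled list includes background regions, so these other summits are not a set of weaker binding sites. Another 24.6% of IDR summits lay outside protein-coding genes, 11.3% in introns and 1.24% in exons, whereas exons hold 24.1% of the nuclear sequence. The median promoter summit was 170 bp upstream of the nearest protein-coding 5′ end, and 92.7% of promoter summits were upstream of it. For promoter summits of the other pooled-list peaks the median was 146 bp upstream, and 75.6% were upstream. The promoter window itself reaches further upstream than downstream.

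**Figure D1:**
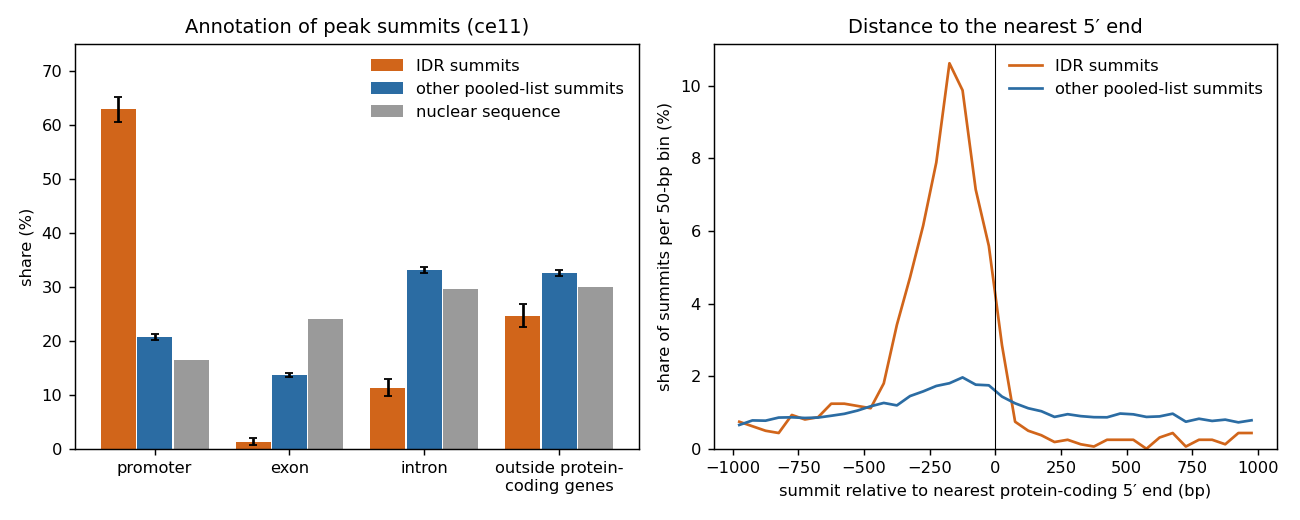
Left, share of IDR summits, of other pooled-list summits and of nuclear sequence in each annotation class, in percent, with 95% Clopper-Pearson intervals on the shares of summits. Right, share of summits per 50-bp bin against distance in bp from the nearest protein-coding 5′ end, where negative values are upstream; promoters held 62.9% of IDR summits, with a median of 170 bp upstream among those.

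Among the 15 IDR peaks of highest signal, 4 were at protein-coding promoters. The peak ranked 2, on chromosome II at 10563436 to 10563722, had a signal of 793 and lay 169 bp upstream of cdc-48.1 (WBGene00007352), which encodes an AAA ATPase that extracts ubiquitylated proteins. The peak ranked 4, on chromosome III at 3867431 to 3867727, had a signal of 772 and lay 283 bp upstream of the ribosomal protein gene rpl-3 (WBGene00004414). The peak ranked 12, on chromosome IV at 4749937 to 4750229, had a signal of 604 and lay between the divergent genes rpl-20 (WBGene00004432) and Y17G9B.5 (WBGene00021202). The peak ranked 13, on chromosome III at 10759101 to 10759390, had a signal of 585 and lay 58 bp upstream of tasp-1 (WBGene00010480). In each replicate list these 4 peaks ranked 15 or higher. Of the other peaks among the 15, 9 were on the X chromosome outside promoters, 1 was on the mitochondrial genome and 1, at 8043850 to 8044106 on chromosome III, was outside protein-coding genes.

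Summits on the X chromosome were less often in promoters than those on the autosomes. Its 3 peaks of highest signal, none of them in a promoter, are named here after their values were seen. The peak ranked 1 had a signal of 812 and lay in an intron of Y41G9A.17, at 2996889 to 2997387. The peak ranked 3 had a signal of 786 and lay in an intron of mom-1, which encodes a protein needed for Wnt secretion, at 6296322 to 6296777. The peak ranked 5, at 11093964 to 11094366, was outside protein-coding genes. In all, 41.1% of the 248 X chromosome summits were in promoters, against 66.8% of the 1363 autosomal summits (Fisher's exact test, odds ratio 0.347, p = 4.59e-14, a comparison chosen after the peaks were seen). The X chromosome held 15.4% (13.7 to 17.3) of nuclear IDR peaks and 17.7% of nuclear sequence (exact binomial test, two-sided, adjusted exact p = 0.017 over 2 tests). Against the 13.7% of protein-coding genes that are on X, the same share was higher (adjusted exact p = 0.046), so the direction of this difference depended on the reference. The lower share did not pass the threshold among the top peaks of replicate 1 alone (16.1%, adjusted exact p = 0.096) or in the 800 nuclear peaks among the 813 IDR peaks of higher signal (16.5%, adjusted exact p = 0.40). Among the nuclear chromosomes, I had 22.6 IDR peaks per Mb (20.2 to 25.1), III had 22.2 (19.8 to 24.8) and V had 10.5 (9.13 to 11.9, exact Poisson intervals). On the autosomes, 818 of 1363 peaks were in the central 50% of the chromosome (95% interval 57.4% to 62.6%, exact binomial adjusted exact p = 2.90e-13). Against the 55.7% expected from protein-coding genes, this share was also higher, by a smaller margin (exact binomial adjusted exact p = 0.0023).

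**Figure D2:**
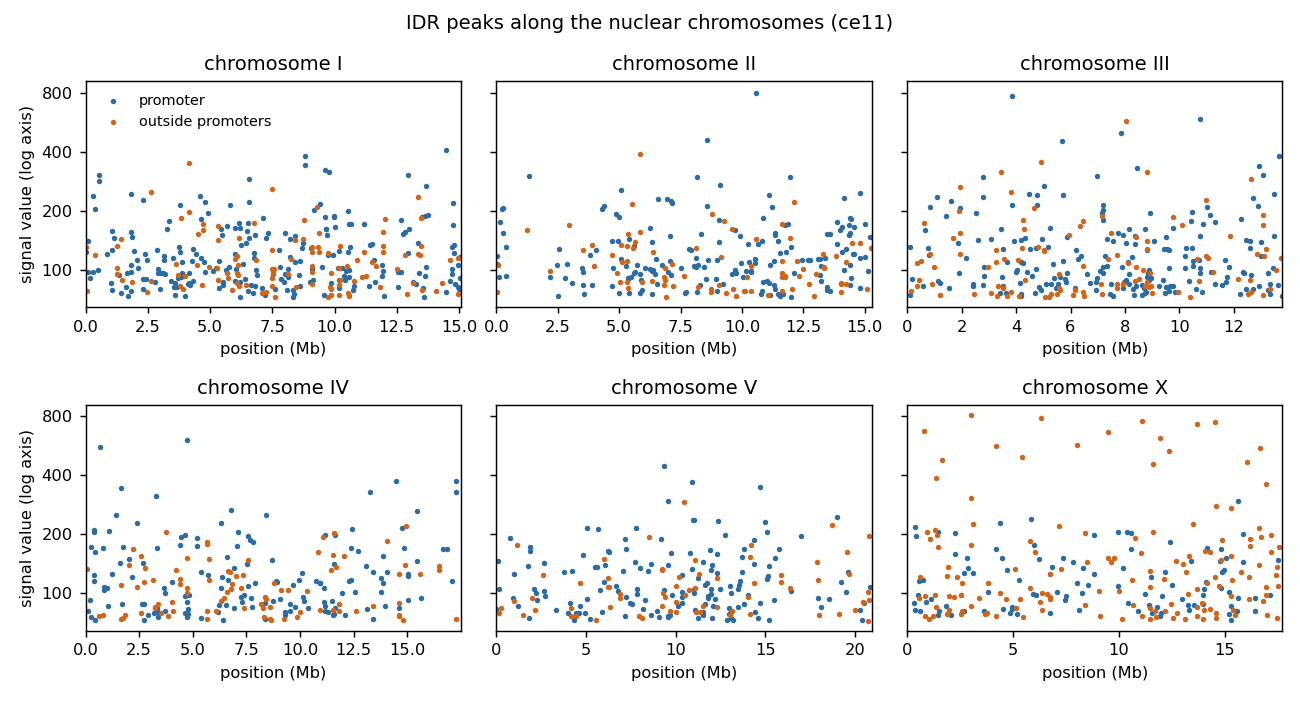
Each point is a nuclear IDR peak, placed by its position in Mb and its signal value on a log axis, and coloured by whether its summit was in a protein-coding promoter. On X, the peaks of highest signal lay outside promoters; the highest had a signal of 812.

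Promoters of genes for protein synthesis, protein turnover and mitochondrial respiration carried IDR peaks more often than other promoters. Of 19973 protein-coding genes, 1336, or 6.69%, had an IDR summit in the promoter window. Ribosomal protein genes had one at 63 of 82 members, or 76.8% (Fisher's exact test, odds ratio 48.5, 95% interval 28.5 to 86, Benjamini-Hochberg adjusted exact p = 3.42e-56 over 24 lists). Members of highest signal were rpl-3, rpl-20, rpl-15 (signal 555) and rpl-35 (signal 499). Proteasome genes had a peak at 17 of 33 members (odds ratio 15, adjusted exact p = 1.63e-11), with rpn-3 (signal 331), rpn-9 (208), pbs-3 (140) and rpn-5 (139) highest. Heat shock and chaperone genes had a peak at 24 of 61 members (odds ratio 9.20, adjusted exact p = 1.70e-12). Among them, hsp-1, a constitutive Hsp70, had a signal of 373, hsp-90 had 347, hsp-110 had 331 and the chaperonin subunit gene cct-1 had 296. The genes hsp-110 and rpn-3 are divergent and shared a single peak. Genes of the mitochondrial respiratory chain had a peak at 25 of 66 members (odds ratio 8.65, adjusted exact p = 1.70e-12), led by cox-5A (signal 338), cox-5B (315), cox-6B (298) and nuo-1 (240), whose summit also lay in the window of the ribosomal protein gene rpl-36.A. Vacuolar ATPase genes, which encode the proton pump of acidic organelles, had a peak at 7 of 20 members (odds ratio 7.55, adjusted exact p = 0.00056). The highest were vha-8 (signal 267), vha-12 (168), vha-1 (164) and vha-15 (159). This call was lost with a window of 300 bp upstream and 100 bp downstream (odds ratio 2.06, adjusted exact p = 0.41).

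The odds ratios of these lists were smaller under some alternatives, and all but the vacuolar ATPase call stayed past the threshold. With each summit given to the nearest gene within 2000 bp, they were 11.9 for ribosomal protein genes (37 of 82), 6.17 for proteasome genes (10 of 33), 3.12 for chaperones (11 of 61) and 5.35 for respiratory chain genes (18 of 66). With a background of genes with a pooled-list summit, they were 6.78 for proteasome genes, 5.34 for chaperones and 4 for respiratory chain genes. With the window of 300 bp and 100 bp, ribosomal protein genes had a peak at 37 of 82 members (odds ratio 15.8).

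Peaks were rarer at 3 large families. Chemosensory receptor genes had a peak at 2 of 1302 members (odds ratio 0.020, adjusted exact p = 3.59e-36; at most 0.051 under the alternatives). These included sri-5, whose peak also lay in the window of rsr-1. Cytochrome P450, glutathione S-transferase and UDP-glucuronosyltransferase genes had a peak at 0 of 185 members, which allows a share of up to 1.97% (adjusted exact p = 1.35e-05). Collagen genes had a peak at 3 of 177 members (odds ratio 0.239, adjusted exact p = 0.0088). Each of these peaks, at col-38, col-2 and col-71, also lay in the window of another gene. The collagen call was lost when the background was restricted to genes with a pooled-list summit (odds ratio 0.437, adjusted exact p = 0.40), and in the 813 IDR peaks of higher signal (odds ratio 0.310, adjusted exact p = 0.20).

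Lists of tissue genes and of transcription factors did not pass the test. Nuclear hormone receptor genes, the family of the tagged factor, had a peak at 13 of 274 members (odds ratio 0.692, 95% interval 0.362 to 1.21, adjusted exact p = 0.36). The odds ratio was 1.11 (20 of 274) with each summit given to the nearest gene and 0.402 (4 of 274) in the 813 IDR peaks of higher signal, and neither passed. The highest were nhr-1 (signal 148), nhr-256 (138), nhr-47 (137) and nhr-34 (110). The summit at nhr-47 also lay in the window of dnj-19, a member of the chaperone list. None of 50 intestine genes had a peak, which allows a share of up to 7.11%. The count was 0 of 33 for hypodermis genes, 0 of 28 for pharynx genes and 0 of 7 for the endoderm GATA cascade. Pharynx genes had a peak at 2 of 28 members among the top peaks of replicate 1 alone and of replicate 2 alone, and hypodermis genes at 3 of 33 by nearest gene. For lists this short the upper limits of 10.6%, 12.3% and 41.0% lie above the share of all genes, so a lower share was not detectable. Body wall muscle genes had a peak at 2 of 35 members, unc-112 (signal 89) and act-4 (83.4). Pan-neuronal genes had a peak at 4 of 32 members, tbb-1 (signal 148), unc-16 (128), ric-19 (123) and snb-1 (109). The summit at tbb-1 also lay in the window of rib-2, and that at ric-19 in that of pmlr-1. The odds ratio of the neuronal list, 2.00, was 3.92 in the peaks of higher signal (adjusted exact p = 0.061), and that of the muscle list, 0.845, was 1.37 among the top peaks of replicate 1 alone and 1.32 by nearest gene. The members of the next lists are named after their values were seen. The counts were 2 of 95 for homeobox factors (ceh-38 and ceh-39), 3 of 39 for basic helix-loop-helix factors (aha-1, hlh-11 and mxl-2) and 1 of 42 for germline and maternal genes (spn-4). They were 5 of 81 for histones (his-37, htz-1, his-67, his-68 and hil-7) and 4 of 101 for fatty acid metabolism (ech-5, lbp-4, cpt-2 and ech-1.2). The count was 1 of 27 for the Wnt pathway, namely mig-5, which shared its peak with cct-1. Adjusted p over these lists was between 0.17 and 1.

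Among non-coding genes other than piRNA genes, 463 of 11554, or 4.01%, had an IDR summit in their window. Small nucleolar and small nuclear RNA genes had one at 55 of 475 members, or 11.6% (odds ratio 3.42, adjusted exact p = 3.76e-12). The highest were the snoRNA gene F54E7.10 (signal 455), the spliced leader genes sls-2.1 (387) and sls-2.4 (349), and the snoRNA gene D1007.20. The summit at F54E7.10 also lay in the windows of rps-12 and ska-3, and that at D1007.20 in those of rpl-24.1 and rps-10. At 21 of the 55 genes, every such summit was also in a protein-coding promoter. Transfer RNA genes had a peak at 62 of 612 members, or 10.1% (odds ratio 2.96, adjusted exact p = 3.11e-11). The 4 of highest signal, WBGene00022908 (218), WBGene00023042 (204), WBGene00022947 (199) and WBGene00023117 (196), were on the X chromosome. The summit at WBGene00022908 also lay in the window of sor-3, and that at WBGene00023117 in that of ZK1193.2. The summit at WBGene00022947 also lay in the windows of C28G1.2 and sec-15. At 12 of the 62 tRNA genes, every such summit was also in a protein-coding promoter. With autosomal peaks and genes only, an alternative chosen after the data were seen, the tRNA call was lost (odds ratio 1.63, adjusted exact p = 0.11). Transfer RNA genes occur in near-identical copies, and how reads that match several copies were placed is not given in the sources used here. MicroRNA genes had a peak at 11 of 262 members (adjusted exact p = 1), but at 22 of 262 with each summit given to the nearest gene (odds ratio 1.83, adjusted exact p = 0.030). The tRNA odds ratio was 1.90 by nearest gene and 1.84 against genes with a pooled-list summit.

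**Figure D3:**
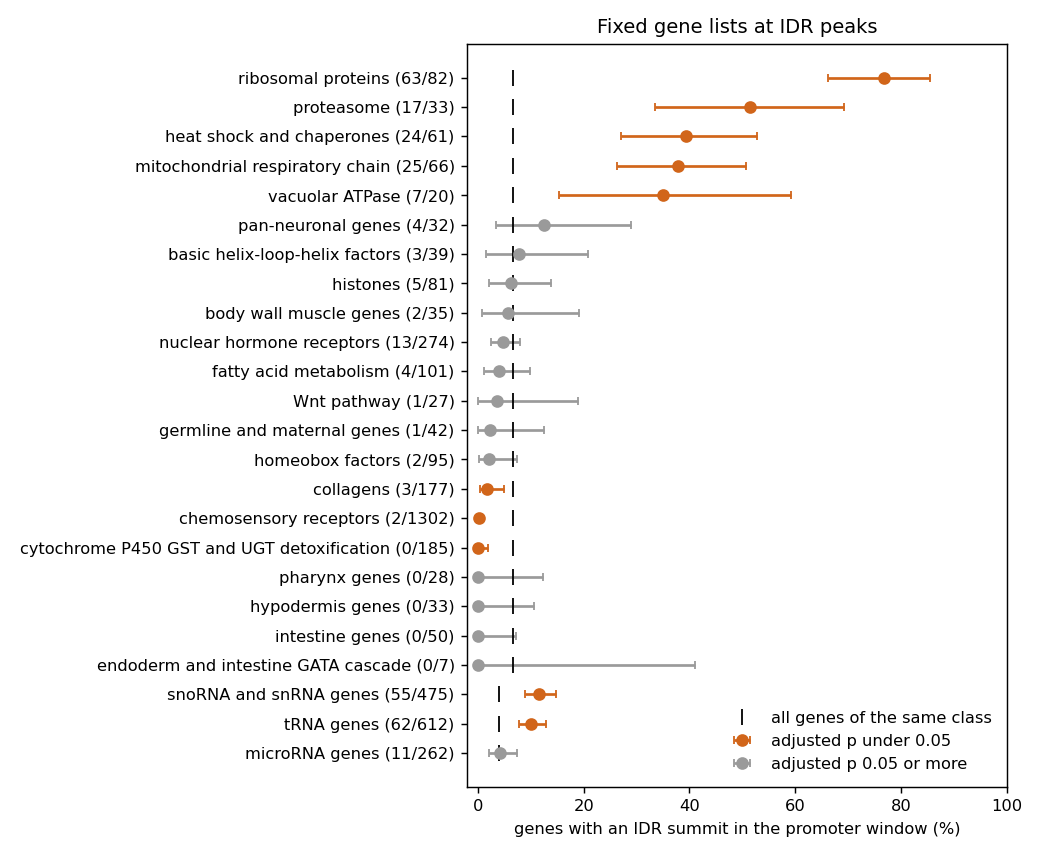
Share of each fixed list, in percent, with an IDR summit in the promoter window, with 95% Clopper-Pearson intervals; counts stand beside the names and vertical ticks mark the share of all genes of the same class. Ribosomal protein genes had the highest share, 76.8%.

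Motif content at the summits was compared with flanks centred 200 bp to either side of the same peaks. Of 20 fixed motifs, 6 were more frequent within 50 bp of the summit and 6 less frequent (exact McNemar test, two-sided, adjusted p under 0.05). The repeat GAGAGA was at 29.2% of 1611 centres and 11.2% of flanks (adjusted exact p = 7.26e-38). GCGTCTC, the core of a promoter motif of C. elegans, was at 12.2% against 1.74% (adjusted exact p = 1.37e-32) and CGAGACC was at 6.89% against 1.06% (adjusted exact p = 2.13e-17). GGGCGG was at 6.77% against 2.23%, CCCGCC at 6.46% against 2.11% and TTGCAC at 8.07% against 4.16%. The less frequent motifs were the GATA site TGATAA (2.98% against 11.1%), the homeodomain core TAATTA (1.24% against 6.15%), TATAAA (5.65% against 11.7%), GAANNTTC (4.84% against 7.82%), CCAAT (15.7% against 18.9%) and AAGTCA (2.73% against 4.28%). The call of CCAAT was lost among the top peaks of replicate 2 alone (adjusted exact p = 0.055), in the 813 IDR peaks of higher signal (0.119) and on the autosomes alone (0.121), with ratios of 0.848, 0.815 and 0.854 against 0.830. That of AAGTCA was lost among the top peaks of replicate 2 alone (adjusted exact p = 0.122) and on the autosomes alone (0.121), with ratios of 0.710 and 0.673 against 0.638. The nuclear receptor core AGGTCA was at 2.05% of centres and 2.42% of flanks (ratio of discordant peaks 0.846, 95% interval 0.516 to 1.38, adjusted exact p = 0.62). The remaining 7 motifs did not pass the threshold. Of these, CAGCTG (3.17% against 1.99%, adjusted exact p = 0.060) and TGTTTAC (2.11% against 1.12%, adjusted exact p = 0.056) passed among the top peaks of replicate 2 alone (adjusted exact p = 0.019 and 0.040). CAGCTG also passed in the 813 peaks of higher signal (adjusted exact p = 0.0039) and against other pooled-list peaks (7.76e-05), and TGTTTAC with flanks centred 500 bp away (0.0023). With those flanks the ratio of centres to flanks rose from 2.60 to 5.28 for GAGAGA, from 7.04 to 16.4 for GCGTCTC, from 3.03 to 5.19 for GGGCGG and from 3.06 to 4.73 for CCCGCC. For CGAGACC it was 6.53, and 3.19 within 100 bp of the summit and 13.8 in the peaks of higher signal. For TAATTA it was 0.202, and 0.463 within 100 bp and 0.339 among the top peaks of replicate 2 alone; for AAGTCA it was 0.638, and 0.405 in the peaks of higher signal. Of 2080 6-mers merged with their reverse complements, 526 were more frequent at the centre and 445 less frequent. The 6-mers of largest ratio were ACGCGC (16.2% against 1.18%), GCGCGC (10.7% against 1.18%), GCACGC (7.64% against 0.87%), AGCGCG (12.97% against 1.49%) and CGCTCC (11.2% against 1.30%). Centres had a GC content of 46.1%, flanks 35.5% and the nuclear genome 35.4%. How far this difference accounts for the less frequent motifs, several of them AT-rich, was not tested.

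**Figure D4:**
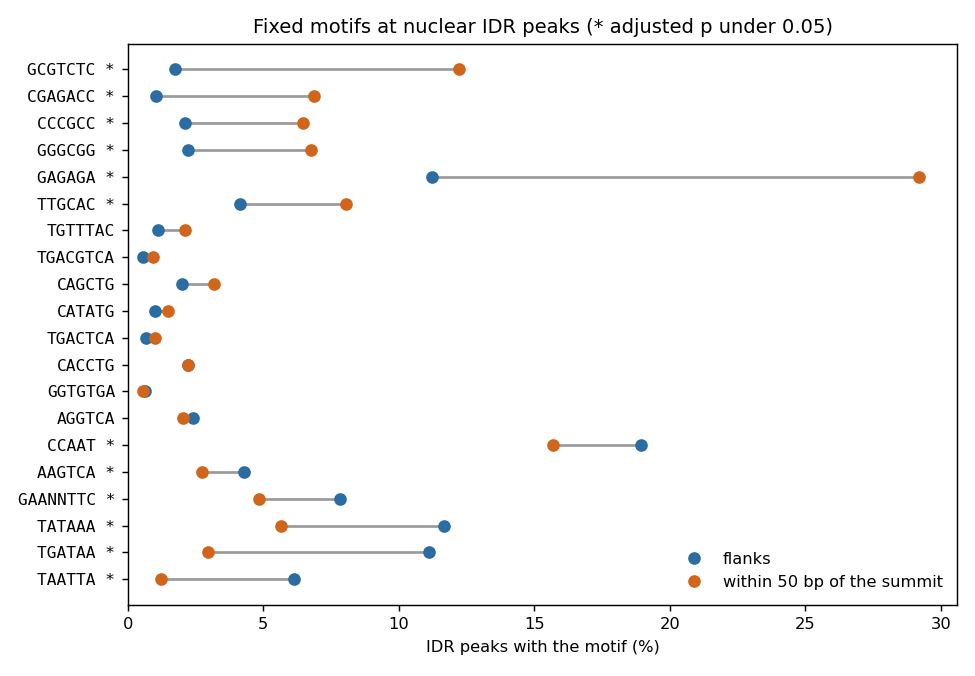
Percent of nuclear IDR peaks with each fixed motif within 50 bp of the summit and in the flanks; a star marks an adjusted p under 0.05. GAGAGA was at 29.2% of centres, and AGGTCA at 2.05% of centres and 2.42% of flanks.

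The loci present on the transgene carried no IDR peak. None lay within 5 kb of nhr-237 (WBGene00021610, chromosome V, 1625189 to 1626820, minus strand), or within 5 kb of unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, plus strand), the selection marker. No peak of either replicate list or of the pooled list lay in the nhr-237 window of 11.6 kb. The unc-119 window of 16.3 kb held 4 replicate 1 peaks, the highest of which ranked 5018 of 10872, and 8 replicate 2 peaks, the highest of which ranked 6075 of 30000. These correspond to 0.245 and 0.491 peaks per kb, against 0.108 and 0.299 per kb over the nuclear genome.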

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

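All tests in this part except those of GCGCAGGG and of repeated sequence were chosen after the result was seen. The mitochondrial genome, which the promoter, chromosome share, gene list and motif comparisons left out, carried 15 IDR peaks on 13.8 kb, or 1087 per Mb against 16.1 per Mb on the nuclear chromosomes. The highest ranked 10 of all IDR peaks, with a signal of 647; it ranked 3 in replicate 2 and no replicate 1 peak overlapped it. Of the 15, replicate 1 peaks overlapped 7, replicate 2 peaks 14 and peaks of both 6. The replicate 1 list held 10 mitochondrial peaks and the replicate 2 list 24. The control was not analysed here, and no explanation was tested.

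The 18 X chromosome peaks among the 40 IDR peaks of highest signal lay outside promoters, and each was within the top 50 peaks of both replicates. The limit of 40 was set after the ranks were seen, and the number depends on it: X peaks outside promoters numbered 12 among the highest 20, 19 among the highest 60 and 21 among the highest 80. With limits of 20 to 80 the share of such peaks with the word GCGCAGGG ranged from 57.1% to 75%. The word was picked once the peak positions and enriched 6-mers were known, but before its own count.

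Sequence repeated exactly in the reference genome is argued against as the source of these X peaks. A median of 0% of the 50-mers within 100 bp of their summits occurred more than once. Copies that differ in sequence or are missing from the reference would not be counted. How reads that match several copies were placed is not given in the sources used here. GCGCAGGG, the core of a motif known from sites that recruit the X chromosome dosage compensation complex, was within 200 bp of 11 of the 18 summits, or 61.1% (35.7 to 82.7). It was near 6 of the 128 other X summits outside promoters, or 4.69% (Fisher's exact p = 2.67e-08), and near 0.23% of random X positions. A hypothesis is that some of these peaks may lie at such recruitment sites, though 7 of the 18 lacked the word. Lists of other factors or of worms without the tag were not analysed here, so it stays open whether the signal depends on NHR-237; the design holds a single group, so no difference between groups was tested.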

How the results depend on the processing

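Promoter share ranged from 51.1% to 72.1%, the overlap of replicate 1 peaks with replicate 2 from 43.8% to 71.6% and signal agreement from rho 0.62 to 0.74. These and the central share of autosomes kept their direction and their side of the threshold under every alternative run on them. The reverse overlap, 25.7% of replicate 2 peaks, was not tested against random placements. The midpoint alternative tested nothing, since it changed the promoter class of 0 peaks. The share of IDR peaks found in both replicates was 93.8% with summits within 100 bp and 94.8% with reciprocal overlap of 50%; both rules are stricter by construction. The X share was 16.5% in the 800 nuclear peaks among the 813 of higher signal, where it no longer passed, and the cause was not tested. It ranged from 15.6% without replicate 1 to 16.1% without replicate 2, and only the latter lost the call; the cause was not tested. Against the share of protein-coding genes, the X share of 15.4% was higher in place of lower, since X holds fewer genes than its sequence share. Within 5 kb of unc-119 there were 8 peaks without replicate 1 and 4 without replicate 2, and the highest of those peaks ranked 6075 and 5018. Within 5 kb of nhr-237 there were 0 in both lists. These lists are longer than the IDR list, and whether that accounts for the counts was not tested. Gene lists past the threshold numbered 8 to 11 against 10; the permutation within deciles of upstream length covered the 21 protein-coding lists only. Motifs past the threshold numbered 10 to 13 against 12. Among single lists and motifs, 9 alternatives ended a call and 6 made one, and 338 left the call as it was. Autosomal peaks only were chosen after seeing the data. Library depth is unknown, so what it limits could not be measured.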

Other observations

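All tests in this part except the composition test over every word were chosen after the results were seen. Gene classes named by a shared symbol prefix were also compared. Of 175 classes with 10 or more members, 19 had IDR peaks at more of their promoters than other genes and 6 at fewer (Fisher's exact test, Benjamini-Hochberg adjusted over the classes). Of these, 7 of the 19 (rpl, rps, rpn, dnj, vha, cox and hsp) and 4 of the 6 (str, srh, srw and srx) were genes of lists already tested. Translation initiation factor genes (eif) had a peak at 12 of 25 members (odds ratio 12.98, adjusted exact p = 1.02e-06), among them eif-3.B (signal 246) and eif-3.C (186). RNA polymerase II subunit genes (rpb) had one at 6 of 11 (odds ratio 16.8, adjusted exact p = 0.00053), nuclear pore genes (npp) at 8 of 26 (odds ratio 6.23, adjusted exact p = 0.0022) and genes of the large mitochondrial ribosomal subunit (mrpl) at 11 of 41 (odds ratio 5.15, adjusted exact p = 0.00089). The mrps class, of the small subunit, had one at 5 of 29 and did not pass (odds ratio 2.91, adjusted exact p = 0.18). The lin class, named by a cell lineage phenotype, had one at 11 of 47 members (odds ratio 4.29, adjusted exact p = 0.0022), among them lin-54 (signal 327), lin-35 (213) and lin-9 (195). The peak at lin-54 also lay in the window of the ribosomal protein gene rpl-12, and that at lin-35 in the window of vps-51. C-type lectin genes (clec) had one at 1 of 240 members, clec-126 (adjusted exact p = 5.69e-05) and F-box genes of the fbxa class at 0 of 170 (adjusted exact p = 0.00031).

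Divergent promoters were frequent. Of 1013 promoter summits, 328, or 32.4% (29.5 to 35.4), lay in windows of genes on both strands, against 5.22% of promoter sequence (exact binomial p = 1.13e-161) and 7.08% of other pooled-list promoter summits (Fisher's exact odds ratio 6.29, p = 1.60e-96). Neither reference was matched for position in the window. IDR promoter summits were upstream of the 5′ end in 92.7% of cases, against 75.6% of the other pooled-list promoter summits. How much of the excess follows from this was not tested. The pooled list had 0 peaks in the nhr-237 window, as did 14.1% of 10000 random windows of that length on chromosome V. It had 9 in the unc-119 window, a number reached by 18.9% of random windows on chromosome III.

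Peaks at promoters of ribosomal protein and other housekeeping genes could reflect signal at highly transcribed genes whatever the factor, which transfer RNA genes 1 kb or more from promoter windows served to test. Their odds ratio of a peak against other non-coding genes was 4.27 over the genome (Fisher's exact p = 9.31e-09), but this rested on X, where it was 6.92 (3.80 to 12.3). On the autosomes, where 4 of 157 such genes had a peak, it was 1.28 (0.336 to 3.46, Fisher's exact p = 0.56), and the strata differed (exact test of homogeneity, p = 0.0029). The split by chromosome was made after the pooled value, which met the criterion then set, had been seen. The autosomal interval is too wide to decide, and transcription was not measured here. Transfer RNA genes are also a different class from protein-coding genes, so a narrower interval would not settle the question for the latter. The explanation stays open, and the single group of the design allows no comparison between groups for this pattern or for GC-rich words. The nuclear receptor core AGGTCA was at 18 of 1013 promoter centres and 22 flanks, and at 0 of 131 centres of the 5 housekeeping lists (upper limit 2.78%), and its variant AAGTCA at 24 promoter centres and 48 flanks (exact McNemar adjusted p = 0.011); no explanation is drawn from these values, which the motif comparison over all peaks had largely fixed.

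GC-rich words at the summits could follow from base and dinucleotide composition, which predicts a ratio of real to dinucleotide-shuffled centres near 1. Over 11 words, the 6 fixed motifs called higher and the 5 6-mers named for the largest ratio, the median was 2.33 (2 to 2.57 over 10 shuffles), and 9 of the 11 were at more centres than in any shuffle. The bound against composition set beforehand was 2, which the lowest shuffle only reached. For the fixed motifs the median was 2.50 (2.35 to 2.92), above that bound in every shuffle. These motifs were kept for being called higher at the same centres, and were not picked again on separate peaks. For the 6-mers, also picked on these centres, the median of 1.92 (1.75 to 2.01) was below the bound. A lower bound that both medians pass was adopted only after the values were seen, so no verdict rests on it. For 6-mers picked by the same rule on odd-ranked peaks and tested on the 805 even-ranked ones, the median was 2.01 (1.63 to 2.07). In the reverse direction it was 2.01 (1.69 to 2.37). Both ranges lay above the ratio near 1 that composition predicts, but their lowest values were below the bound of 2. For the 6-mers, whether composition is the whole cause therefore stays open. For the 6 fixed motifs as a set, the median above 2 in every shuffle argues against composition as the whole cause. Their ratio was 8.24 for CGAGACC, 8.02 for GCGTCTC and 2.60 for GGGCGG. It was 2.39 for GAGAGA, 2.33 for CCCGCC and 1.17 for TTGCAC. The limit remains that these motifs were called on the same centres. For TTGCAC and GCACGC, the words not above every shuffle (median 1.12), composition cannot be told apart from a sequence preference, since they were singled out by this same result.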
